A study of Caenorhabditis elegans with 63 samples.

How the data were processed

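Small RNA was sequenced from total RNA of whole worms, extracted with Trizol from animals grown at 20 °C, per the labels. One set of libraries was made with the NEBNext small RNA kit and size selection, and the other with adaptors that carry degenerate bases, per the labels. The deposited NEBNext table holds raw reads of miRNAs and spike-ins, per the file headers. The bias-minimized table carries no such statement, and its values, which give different totals per library, were taken to be raw reads as well. Any filter on its reads is not given in the sources used here. Each table has 276 mature arms of 138 hairpins and 10 plant spike-ins, and 274 arms are in both. HTSeq was used, per the submitters' processing notes. Its version, the aligner, the trimming, the genome build and the miRNA annotation are not given in the sources used here. The labels give no amount of spike-in RNA and do not say that it was equal in all libraries.

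Most values are whole, but 292 values of the NEBNext table (4.64%) and 166 of the bias-minimized table (1.42%) were not whole, always in both arms of a hairpin together. All of them lay midway between whole numbers, so the deposited values were treated as estimated counts (expected counts) and rounded to whole numbers before the count tests. An arm name with a star is the rarer strand as the files name it. Near-identical arms of 1 family can share reads, and how the authors' counting divided such reads is not given in the sources used here, so single members of close families (such as mir-44 and mir-45) are uncertain.

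Groups were taken from the labels alone. Before averaging, 57 pairs of libraries of the same group were compared; the lowest chi-square per degree of freedom was 19.5, so no pair agreed within sampling noise and each library counts as 1 sample. Depth ranged from 155736 to 5565918 miRNA reads per library; the biological coefficient of variation was 0.123 in the 18 NEBNext libraries of wild type, cdb328 and cdb330, 0.598 in the bias-minimized Adults and 0.574 in the mir-80 series.

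Comparisons, tests, lists and the naming rule were chosen before the data were examined. Each count of changed miRNAs and each fold change came from edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM normalization on the miRNA counts without spike-ins, filterByExpr (minimum count 10, minimum total count 15), glmQLFit and glmQLFTest with one coefficient per group, and Benjamini-Hochberg adjustment with a threshold of 0.05. A separate fit was made for the 18 NEBNext libraries of wild type, cdb328 and cdb330 (215 arms tested), for all 22 NEBNext libraries (215; used for the tagged strains), for the 9 bias-minimized Adults (191) and for the 32 libraries of the mir-80 series (207). Standard errors are those implied by the F statistic. The stage interactions and the differences of drsh-1 effects between mir-80 alleles were contrasts of 4 groups in the same fits.

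The miRNAs named in the text followed a rule. Per comparison it takes the 8 largest falls and the 8 largest rises (5 in the mir-80 series) among those past the threshold with a mean of at least 10 CPM whose libraries do not overlap between groups. It adds a fixed set (both arms of mir-80, and the main arms of mir-81, mir-82, mir-58a, let-7, lin-4, mir-35, mir-1 and mir-71, with the mirtrons), and the 2 to 4 members of each list with the smallest p. Not every miRNA that the rule allows is printed. miRNAs counted over the 9 drsh-1 comparisons were chosen after their values were seen.

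The lists were the let-7, lin-4, miR-35, miR-44, miR-51, miR-58, miR-64, miR-72 and miR-238 seed families, mirtrons (mir-62, mir-1018, mir-1019 and mir-1020, of which only arms of mir-62 were tested) and neuronal miRNAs (lsy-6, mir-124 and mir-791), with both arms of a hairpin counted. Each list was tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Correlations across miRNAs or hairpins used permutation tests with 100000 resamples (10000 in the closing section), and differences of a single value between groups exact two-sided permutation tests.

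Alternatives were DESeq2's size factors in edgeR, total counts, scaling on mirtrons, which are made without Drosha, no filter, DESeq2 1.42.0 with its Wald test, fits of only the groups compared, and the replicate number as a block. Others were the estimated correlation, only miRNAs of at least 100 CPM in the correlations, the bias-minimized Adults as reference effect for cdb530, and leaving out each library in turn. Added after seeing the data were scaling on the spike-ins (median of ratios over the 10), a robust fit, fits without the miRNAs lost from some bias-minimized libraries, fits without these and every miRNA whose CPM differed over 15-fold within at least 2 groups (the higher value over 300 CPM), a technical class as a covariate in the mir-80 series, and a fit without the miR-35 family. On the spike-in scale the NEBNext fit estimated a single spread for all miRNAs, so its adjusted p-values are not printed. The counts of calls on that scale rest on the same single spread.

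Whether equal replicate numbers pair the samples was checked by the correlation of their deviations from the group means. In the bias-minimized Adults every one of 9 same-numbered pairs correlated above 0.1 (mean 0.551, lowest 0.103), and 8 of 9 libraries correlated best with their own number. There the numbers were taken to pair the samples. Same-numbered NEBNext libraries had a mean correlation of only 0.0112, and library names hint that the Adult RNA may be the same. Paired worms and a link made in library preparation therefore cannot be told apart. With the number as a block, 94, 1 and 69 arms were called in the 3 comparisons, as without it, and no named miRNA of these comparisons changed its call.

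The procedure was tested on simulated data drawn from the real means and library sizes with 40 changed miRNAs. For cdb328 against wild-type Adults with NEBNext (207 miRNAs) 77.8% of 2-fold and 100% of 4-fold changes were recovered. For the tagged strains (213) the values were 89.5% and 100%, for cdb328 with the bias-minimized protocol (187) 25% and 84.2%, for drsh-1(cdb263 cdb328) in the mir-80 series (204) 40% and 70%, and for the difference of drsh-1 effects on cdb493 (205) 0% and 65%. False calls among unchanged miRNAs were 1, 1, 1, 1 and 2. A missing call in the bias-minimized tables therefore says little about changes near 2-fold.

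Positions are those of the hairpin genes in the Ensembl 115 annotation of WBcel235, matched by name (137 of 139 hairpin names). The build used by the authors is not given in the sources used here. No genome sequence was used, so hairpin sequences and the changes in the mir-80 and drsh-1 alleles were not analysed here.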

Results

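Small RNAs of whole Caenorhabditis elegans were sequenced to ask how mutations in drsh-1, the worm gene for Drosha, affect individual microRNAs (miRNAs). Drosha is the nuclear RNase III that cuts the hairpin of a miRNA out of its primary transcript, and the series concerns a disordered part of the protein. The labels name the drsh-1 alleles cdb328 and cdb330, and the double-named allele cdb263 cdb328, without saying what sequence each changes, and miRNA reads do not measure drsh-1 mRNA itself. Worms were grown at 20 °C. The 63 libraries fall into 23 groups. Of these, 22 libraries in 8 groups were made with the NEBNext kit from worms in the L4 larval stage or from Adults: wild type, drsh-1(cdb328) and drsh-1(cdb330) at both stages (n = 3 each), and 2 tagged Adult groups (n = 2 each). Both have a GFP tag on drsh-1 and an mScarlet tag on tdp-1, the worm relative of TDP-43, and the second carries in addition the term drsh-1(null) in its genotype. The other 41 libraries, in 15 groups, were made with adaptors that carry degenerate bases to lessen ligation bias, called bias-minimized here. They are wild type, cdb328 and cdb330 Adults (n = 3 each) and 12 groups (n = 2 or n = 3) called the mir-80 series here. These combine 5 alleles of the miRNA gene mir-80 with wild-type or mutant drsh-1, and the labels do not give their stage.

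NEBNext libraries held between 1891780 and 5565918 miRNA reads (median 2424201.5), bias-minimized Adult libraries between 578859 and 2585561, and libraries of the mir-80 series between 155736 and 2355231. Each also held reads of 10 plant miRNAs used as spike-ins, which made up 13.3% to 36.1% of the reads with NEBNext and 37.6% to 63.3% with the bias-minimized protocol. Worm miRNA reads over the spike-in size factor (median of ratios over the 10) were 1.5-fold higher in cdb330 than in wild-type L4 worms and 0.948-fold in cdb328; over summed spike-in reads these values were 1.43-fold and 0.910-fold. In Adults the size-factor ratio of cdb328 to wild type was 0.858-fold with NEBNext and 0.776-fold with the bias-minimized protocol (0.868-fold and 0.806-fold over summed reads). Over 12 such size-factor comparisons no value reached an adjusted p below 0.05; the 1.5-fold difference had an exact two-sided permutation p of 0.1 (n = 3 per group, Benjamini-Hochberg adjusted 0.2), the smallest that 3 against 3 libraries allow. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples.

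The mir-80 gene was measured first in every library of its series, as a check of the labels. miR-80-3p, the main product of mir-80 (WBcel235, III:8865270-8865367, minus strand, intergenic) and a member of the abundant bantam-like miR-58 family, made up 7.35% ± 1.17 (SD, n = 3) of miRNA reads in wild type of the mir-80 series and 7.27% ± 0.918 (n = 3) in drsh-1(cdb263 cdb328). All 5 mir-80 alleles lay below wild type with drsh-1 intact: 0.195% ± 0.00859 in cdb493 (n = 3), 2.65% ± 0.290 in cdb494 (n = 2), 2.28% ± 0.0472 in cdb495 (n = 2), 0.907% ± 0.104 in cdb496 (n = 3) and 1.61% ± 0.0651 in cdb530 (n = 3). No library of a mir-80 mutant reached the wild-type range of 62624 to 85831 CPM. In the groups with wild-type mir-80 outside the series, miR-80-3p took 5.27% to 8.67% of miRNA reads with NEBNext.

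In drsh-1(cdb328) a small set of miRNAs fell to a small fraction of the wild-type level at both stages. miR-71-5p, which promotes long life and stress resistance in worms, fell 23.8-fold at L4 (log2 fold change -4.57 ± 0.15, SE, n = 3 per group) and 38.2-fold in Adults (-5.26 ± 0.15), where it went from 158038.5 ± 27042.8 (SD) to 4132.1 ± 272.5 CPM. Its passenger strand, miR-71-3p* (the star marks the rarer arm as the files name it), fell 57.2-fold and 43.2-fold. miR-54-3p fell 16.9-fold and 12.3-fold, and miR-241-5p, a sister of let-7 that acts in larval timing, fell 10.9-fold and 14.7-fold. miR-790-5p fell by a log2 of 5.45 at L4 and 3.95 in Adults. The hairpins lie apart in the genome: mir-71 at I:9379927-9380020 in an intron of ppfr-1, mir-54 at X:13144996-13145094 in an intron of F09A5.3 on the opposite strand, mir-241 at V:14366188-14366283 and mir-790 at IV:5566422-5566491, both intergenic. The gene drsh-1 itself is at I:9781324-9785724.

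Further down the list both arms of mir-72, mir-73, mir-84 and mir-86 fell. miR-73-3p fell by a log2 of 1.53 at L4 and 2.12 in Adults, miR-72-5p by 1.13 and 1.67, miR-86-5p by 1.02 and 1.41, and miR-84-5p by 1.04 and 1.09. miR-248-3p had -1.40 ± 0.13 and -1.73 ± 0.14, and miR-355-5p -2.72 ± 0.13 at L4 and -1.45 ± 0.12 in Adults. Several rarer arms fell while their partner arm rose on the TMM scale: miR-44-5p* changed by -0.73 and -1.41 against 0.47 and 0.54 of miR-44-3p, and miR-80-5p* by -0.33 and -0.41 against 0.50 and 0.62 of miR-80-3p.

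Rises in cdb328 were smaller. lsy-6-3p, which sets left-right asymmetry of a pair of taste neurons, rose by 1.66 ± 0.25 at L4 and 1.18 ± 0.33 in Adults, miR-1821-3p by 1.57 ± 0.20 and 1.56 ± 0.27, miR-238-3p by 0.81 ± 0.09 and 1.05 ± 0.09, and miR-64-5p by 0.89 ± 0.10 and 0.74 ± 0.10. miR-62-3p, a mirtron whose hairpin (X:12692608-12692665, an intron of ugt-50) is released by splicing without Drosha, rose by 1.07 ± 0.14 and 1.51 ± 0.14. The developmental timers lin-4-5p (0.19 ± 0.10 and 0.03 ± 0.10) and, in Adults, let-7-5p (-0.05 ± 0.12) did not pass the test, while let-7-5p rose slightly at L4 (0.31 ± 0.12). The muscle miRNA miR-1-3p rose by 0.52 ± 0.13 at L4 and had 0.28 ± 0.13 in Adults, which did not pass.

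By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 123 of 215 miRNA arms differed between cdb328 and wild type at L4 (67 higher, 56 lower; 9 at least 2-fold higher and 38 at least 2-fold lower) and 106 in Adults (39 higher, 67 lower; 7 and 48 at least 2-fold). Adjusted p was 3.48e-18 and 7.28e-19 for miR-71-5p, 3.48e-18 and 3.37e-17 for miR-54-3p, and 5.15e-07 and 3.12e-09 for miR-62-3p. The split between higher and lower depends on what is held constant. On the spike-in scale, which moved the log2 fold changes of single miRNAs by a median of -0.29 at L4 and -0.15 in Adults (called median shift below), it was 15 higher and 65 lower at L4 and 23 higher and 70 lower in Adults. Scaling on the mirtrons, which rests on miR-62-3p almost alone and had median shifts of -1.08 and -1.54, left 1 higher and 170 lower at L4 and 0 higher and 188 lower in Adults. With total counts (median shift -0.18 at L4) it was 43 higher and 64 lower at L4. The 2 stages, which share no libraries, had 52 lower arms in common where independent lists would share 17.5, and 36 higher arms where 12.2 would be shared (one-sided Fisher's exact p of 3.02e-31 and 5.59e-19, across miRNAs, which are not independent replicates).

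Families fixed beforehand by seed sequence did not move as blocks. In the miR-72 family (mir-72, mir-73 and mir-74) 5 of 6 arms fell and none rose at either stage (median -1.33 at L4 and -1.90 in Adults). Its miR-74-3p, however, was lower in 0 and higher in 2 of the 9 drsh-1 comparisons counted below (log2 fold changes from -0.12 to 0.81). Camera gave the miR-72 family an adjusted p of 0.0490 at L4 (adjusted p = 0.131 with an estimated correlation) and 0.00179 in Adults (adjusted p = 0.0209 with an estimated correlation). Of 12 arms of the let-7 family 4 rose and 5 fell at L4, and 1 rose and 5 fell in Adults: both arms of mir-241 and mir-84 fell at both stages, while let-7 and mir-48 did not fall (miR-48-5p 0.39 ± 0.10 and 0.02 ± 0.10). In the miR-51 family 3 of 11 arms rose and 4 fell at L4 and 1 rose and 5 fell in Adults, led by mir-54. In the miR-58 family 2 of 9 arms rose and 4 fell at L4, and 1 rose and 4 fell in Adults, the falling arms all being the rarer 5p strands. The miR-64 family had 6 of 10 arms higher and 0 lower at L4 and 3 higher and 1 lower in Adults, but its median went from 0.47 to -0.62 at L4 with mirtron scaling and from 0.11 to -0.06 in Adults on the spike-in scale. In the miR-35 family, which is abundant in embryos, 6 of 16 arms were higher at L4 and 0 lower (median 0.27, -0.80 with mirtron scaling), and in Adults 1 was higher and 5 lower. The miR-44 family had 4 of 7 arms higher and 2 lower at L4 and 3 higher and 2 lower in Adults, and its medians of 0.47 and 0.23 became -0.61 and -1.37 with mirtron scaling. Of the lin-4 family (3 arms) 1 rose and 1 fell at L4 and 0 changed in Adults. Of the miR-238 family (5 arms) 2 rose at L4 and 1 in Adults, although its medians of 0.47 and 0.38 became -0.58 and -1.17 with mirtron scaling. Of the neuronal list (4 arms) only lsy-6-3p rose at either stage. Adjusted over the list alone, these counts differed in 2 places: 5 higher arms of the miR-44 family at L4 and 0 higher arms of the miR-35 family in Adults.

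**Figure D1:**
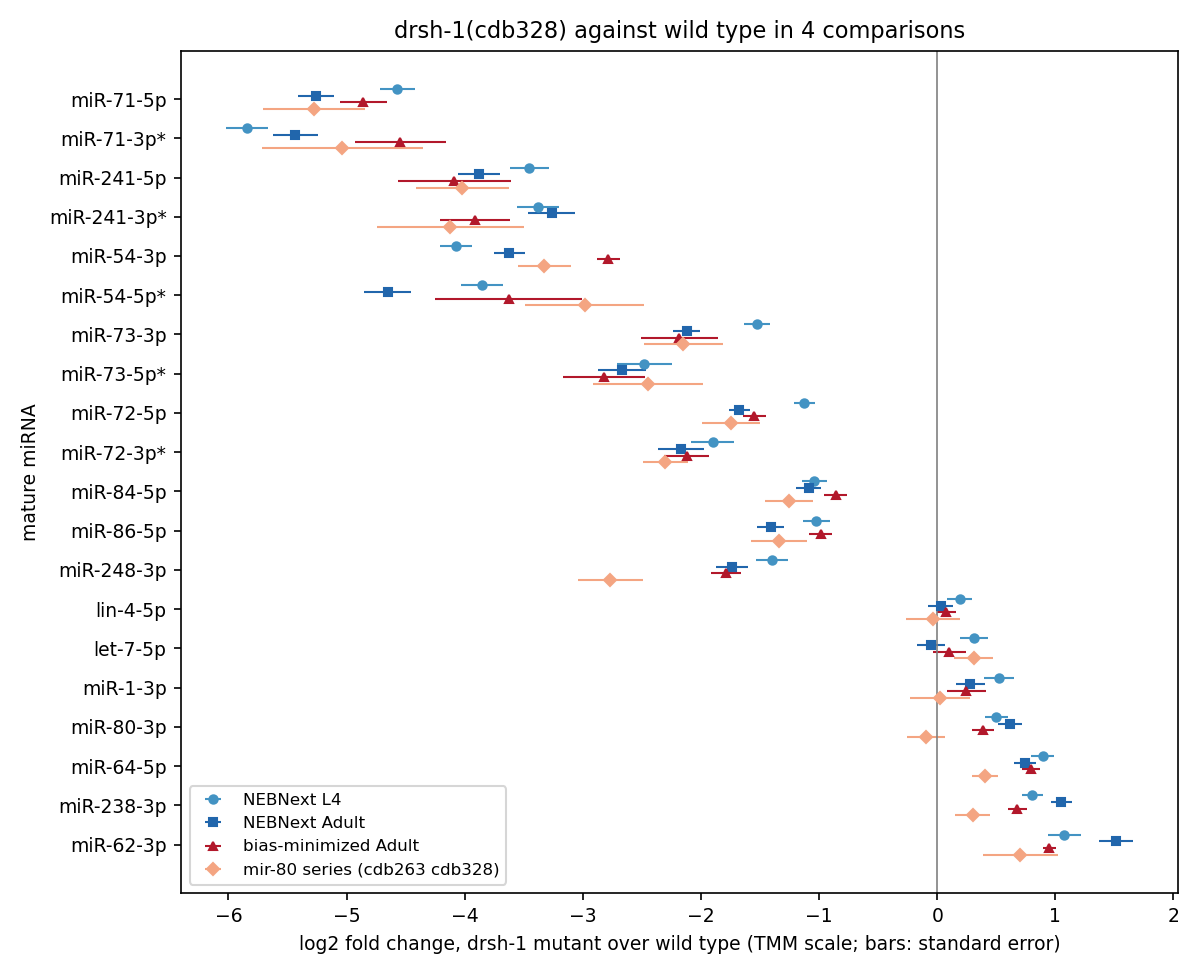
Log2 fold changes of 20 mature miRNAs in a drsh-1 mutant over wild type on the TMM scale (x axis, with standard errors as bars). Each miRNA is on the y axis and 4 comparisons are shown as symbols. The mutant is drsh-1(cdb328), except in the mir-80 series, where it is drsh-1(cdb263 cdb328) and the stage is not labelled. miR-71-5p lies between -5.28 and -4.57 in all 4, while lin-4-5p and let-7-5p lie near 0; the positive values of miR-64-5p, miR-238-3p and most other rising miRNAs turn negative when scaled on the mirtrons.

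The bias-minimized protocol asked whether these changes hold with other adaptors. In Adults, miR-71-5p fell 29.0-fold (-4.86 ± 0.20, n = 3 per group), miR-241-5p had -4.09 ± 0.48, miR-54-3p -2.78 ± 0.10, miR-73-3p -2.18 ± 0.33 and miR-72-5p -1.55 ± 0.10, all past the threshold. The passenger strand lin-4-3p* fell by a log2 of 2.28, while lin-4-5p had 0.08 ± 0.08 and was not called. Among rises, miR-792-3p had 1.75 ± 0.31, miR-124-3p, a neuronal miRNA, 1.14 ± 0.13, miR-62-3p 0.95 ± 0.06 and miR-64-5p 0.80 ± 0.08. By the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment 94 of 191 arms differed (46 higher, 48 lower; 8 and 34 at least 2-fold), with adjusted p of 2.20e-06 for miR-71-5p. The split was 30 higher and 52 lower with total counts, 5 higher and 73 lower on the spike-in scale (median shift -0.51) and 1 higher and 134 lower with mirtron scaling. All 6 arms of the miR-72 family lay at a median of -1.84, with 4 lower and 0 higher (camera adjusted p of 0.0183; adjusted p = 0.182 with an estimated correlation). The miR-238 family had 4 of 6 arms higher (camera adjusted p of 0.0426; adjusted p = 0.182 with an estimated correlation), of which 1 was left on the spike-in scale, and its median of 0.58 became -0.36 with mirtron scaling. Counts for the other lists were 1 higher and 4 lower of 9 arms in the let-7 family, 0 and 6 of 16 in the miR-35 family, 1 and 7 of 12 in the miR-51 family, 3 and 2 of 8 in the miR-58 family, 5 and 2 of 8 in the miR-44 family and 5 and 0 of 10 in the miR-64 family. The medians of the last 2 (0.23 and 0.28) became -0.29 and -0.24 on the spike-in scale. Both neuronal arms tested were higher, 1 of 2 mirtron arms was higher, and 1 of 3 lin-4 family arms was higher and 1 lower. The neuronal arm lsy-6-3p rests on few reads, with 2.04 ± 1.56 CPM (SD) in wild type. Adjusted over the list alone, 2 arms of the let-7 and of the miR-51 family were higher and 3 of the miR-58 family lower, and the other counts were the same.

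Across the 180 miRNAs tested with both protocols, the Adult log2 fold changes of cdb328 had a Pearson r of 0.906 and a Spearman rho of 0.826 (permutation p of 1e-05 for both, the smallest that 100000 resamples give; Benjamini-Hochberg adjusted 2e-05 and 1e-05 over the 2 alleles). These values are across miRNAs, which are not independent replicates, and library names hint that the RNA may be the same. With both protocols 37 arms were lower, where independent lists would share 12.7, and 26 were higher, where 8.6 would be shared, and 0 were called in opposite directions. For cdb330 the same correlation was r = 0.207 (permutation p of 0.01) and rho = 0.447 (1e-05).

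Worms with drsh-1(cdb263 cdb328) in the mir-80 series showed the same leading falls against their own wild type (n = 3 per group). miR-71-5p fell 38.7-fold (-5.28 ± 0.43), miR-790-5p had -6.27 ± 0.94, miR-241-5p -4.02 ± 0.40, miR-54-3p -3.33 ± 0.22 and miR-73-3p -2.15 ± 0.33, and miR-64-5p rose by 0.40 ± 0.11. miR-80-3p had -0.10 ± 0.16 and was not called. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 43 of 207 arms (11 higher, 32 lower; 5 and 27 at least 2-fold), with adjusted p of 2.73e-09 for miR-71-5p; on the spike-in scale (median shift -0.13) 0 were higher and 24 lower, and with mirtron scaling 0 and 50. Leaving out wild type replicate 1 or replicate 2 each lowered the count to 28. In the let-7 family 5 of 10 arms fell and 0 rose (median -0.87, camera adjusted p of 0.00190, and adjusted p = 0.00799 with an estimated correlation), and in the miR-72 family 4 of 6 fell and 0 rose (median -1.95, 0.00856, and adjusted p = 0.132 with an estimated correlation). The miR-51 family had 4 of 12 arms lower, the miR-58 family 2 of 8, the miR-44 family 1 of 8, and the miR-64 family 2 of 10 arms higher (median 0.24, -0.47 with mirtron scaling); adjusted over the list alone the miR-58 family had 4 lower. The miR-44 and miR-58 lists hold miR-44-3p, miR-45-3p and miR-58a-3p, which are among the 20 miRNAs of wide range described next. Other lists hold some of the 20 too. Among them are miR-35-5p*, miR-36-5p* and miR-41-5p* of the miR-35 family and miR-238-5p* of the miR-238 family. Counts of these lists with the bias-minimized protocol include them. No arm of the miR-35, lin-4, miR-238, mirtron or neuronal lists was called. Of the 11 rises, miR-236-3p (6.47 ± 2.21) and miR-79-3p (6.12 ± 2.17) belong to 20 miRNAs of the bias-minimized table that differed over 15-fold between libraries of the same group in at least 2 groups (the higher value over 300 CPM), and are not read as genotype effects. Of the 20, 10 did so in Adult groups too, miR-75-3p, miR-79-3p, miR-87-3p, miR-35-5p* and miR-41-5p* among them. With these and the other lost miRNAs left out (21 in all), 48 arms were called here (23 higher, 25 lower) and 85 in bias-minimized cdb328 Adults (41 higher, 44 lower).

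Counted over 9 comparisons of a drsh-1 genotype that contains cdb328 with its own control (NEBNext L4 and Adult, bias-minimized Adult, and the mir-80 series on wild-type mir-80 and on each of 5 mir-80 alleles), which share no libraries, 179 arms were tested in all and 18 were lower in all. Library names hint that the NEBNext and bias-minimized Adult comparisons may rest on the same RNA. The 18 are both arms of mir-71, mir-241, mir-54, mir-73, mir-72, mir-84 and mir-86, together with miR-248-3p (median -2.49), miR-1817-5p (-1.82), miR-77-5p* (-1.76) and miR-259-5p (-1.41). miR-71-5p ranged from -5.97 to -4.57. The only arm higher in all 9 was miR-64-5p (0.37 to 0.89), whose sign turned with mirtron scaling in each of the 4 comparisons on wild-type mir-80.

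On the TMM scale the cdb330 allele changed fewer miRNAs than cdb328 (66 against 123 at L4 and 16 against 106 in NEBNext Adults). On the spike-in scale it changed more at L4 (143 against 80), but those counts rest on a single spread for all miRNAs. miR-355-5p, which is made from an intergenic hairpin at II:11833536-11833645, fell 14.4-fold at L4 (-3.85 ± 0.14, n = 3 per group), 4.56-fold in NEBNext Adults (-2.19 ± 0.13) and 4.41-fold in bias-minimized Adults (-2.14 ± 0.16). At L4 the miR-35 family fell together: 14 of 16 arms were lower and 0 higher (median -1.66; 15 lower adjusted over the list alone), among them miR-35-3p (-1.70 ± 0.18), miR-36-3p (-1.83 ± 0.15), miR-38-3p (-1.84 ± 0.19) and miR-41-3p (-2.37 ± 0.30). The 2 arms of the list that were not called come from mir-42 (miR-42-3p -0.26 ± 0.16), which lies outside the mir-35 to mir-41 cluster (II:11537608-11538404, in an intron of Y62F5A.9 on the opposite strand). On the spike-in scale 14 arms were also lower (median -1.02). In cdb330 Adults 0 of the 16 arms were called (median -0.11; miR-35-3p -0.11 ± 0.17).

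miR-71-5p, among the strong falls of cdb328 though not the largest, had -0.55 ± 0.13 in cdb330 L4 worms and turned to 0.09 on the spike-in scale. In cdb330 Adults it had -0.19 ± 0.13 and was not called. miR-241-5p rose at L4 (0.84 ± 0.15), as did miR-4813-3p (1.14 ± 0.23), miR-245-3p (0.91 ± 0.18) and lsy-6-3p (0.76 ± 0.25). In Adults miR-77-5p* (-1.49 ± 0.21), miR-790-5p (-1.20 ± 0.23) and miR-253-3p (-1.13 ± 0.21) fell, and miR-4813-3p (0.79 ± 0.24) and miR-80-3p (0.39 ± 0.10) rose; miR-80-3p fell at L4 (-0.31 ± 0.10) but had 0.33 on the spike-in scale. let-7-5p had 0.29 ± 0.12 at L4 and 0.13 ± 0.12 in Adults, and lin-4-5p 0.00 ± 0.10 and 0.23 ± 0.10, none of them called.

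**Figure D2:**
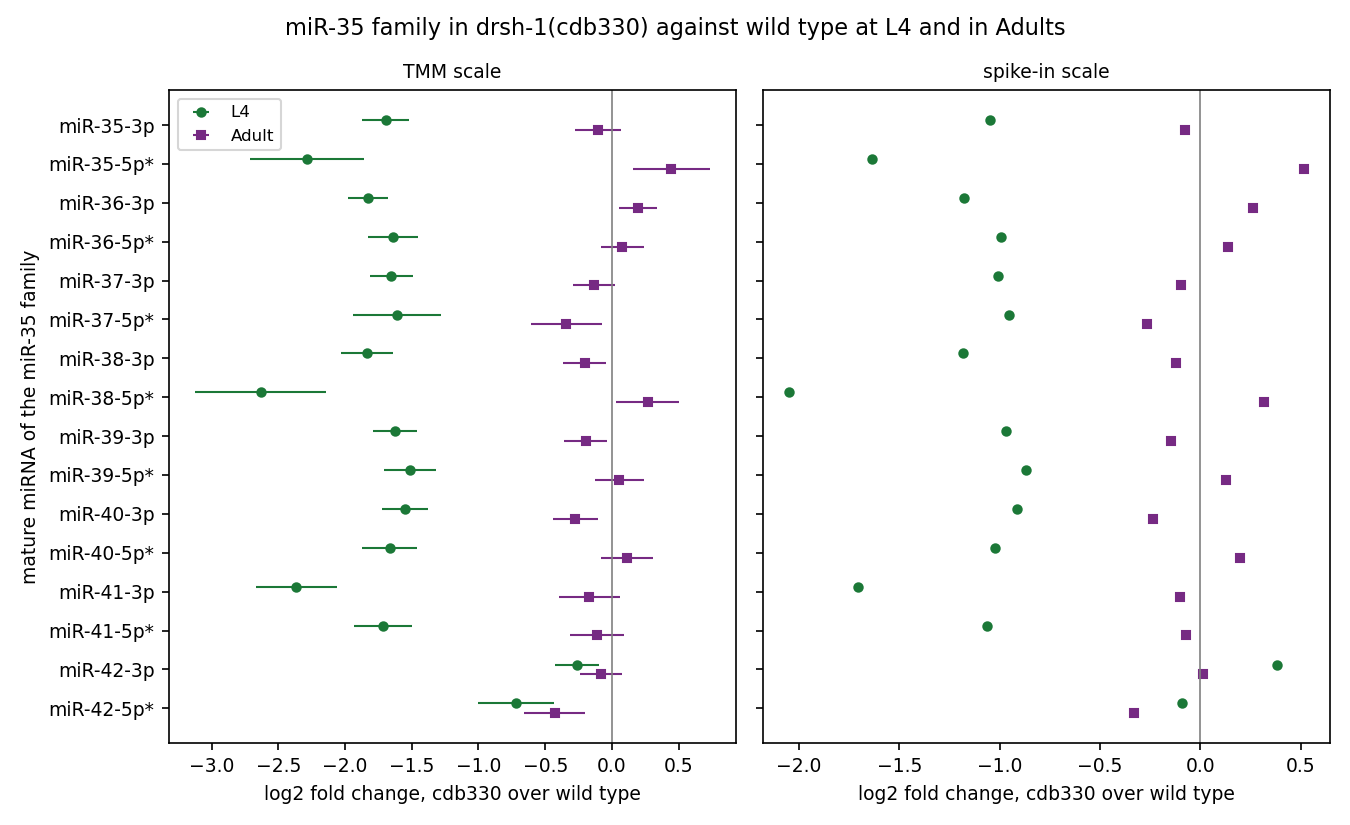
Log2 fold change in drsh-1(cdb330) over wild type (x axes) of the 16 arms of the miR-35 family (y axis) at L4 (circles) and in Adults (squares), on the TMM scale with standard errors (left) and on the spike-in scale (right). At L4 14 arms lie below 0 on both scales and passed the test, while Adult values lie around 0; miR-42-3p changes sign between the scales at L4.

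By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 66 of 215 arms differed between cdb330 and wild type at L4 (22 higher, 44 lower; 2 and 20 at least 2-fold), 16 in NEBNext Adults (6 higher, 10 lower; 0 and 5 at least 2-fold) and 1 of 191 in bias-minimized Adults. Adjusted p of miR-355-5p was 5.15e-17, 2.43e-12 and 3.74e-04 in the 3 comparisons. At L4 the split was 34 higher and 36 lower with total counts and 126 higher and 17 lower on the spike-in scale (median shift 0.64). In NEBNext Adults it was 0 and 45 with mirtron scaling (median shift -0.45) and 3 and 9 on the spike-in scale. The Adult count was 10 without cdb330 replicate 2. For the bias-minimized Adults, 37 arms had an unadjusted p under 0.05, DESeq2 called 23 (12 higher, 11 lower), and other scalings called 4 higher and 3 lower (size factors of DESeq2), 6 and 4 (total counts), 1 and 1 (spike-ins) and 0 and 32 (mirtrons); without wild type replicate 1 the count was 4. Camera gave the miR-35 family at L4 an adjusted p of 1e-15 (adjusted p = 0.0301 with an estimated correlation).

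Among the other lists at L4, 4 of 12 arms of the let-7 family rose and 0 fell (10 rose on the spike-in scale), and 1 of 4 neuronal arms rose. In the miR-44 family 3 of 7 arms fell, in the miR-58 family 1 rose and 4 of 9 fell and in the miR-72 family 4 of 6 fell (5 adjusted over the list alone), but their medians of -0.28, -0.31 and -0.58 became 0.35, 0.33 and 0.06 on the spike-in scale. In the miR-51 and miR-64 families 1 arm each fell (0 in the miR-64 family adjusted over the list alone), and 0 arms of the lin-4, miR-238 and mirtron lists were called. In NEBNext Adults 1 of 9 arms of the miR-58 family rose and 1 fell, and the other lists had 0 called arms. Adjusted over the list alone, 2 arms of the miR-238 family and the mirtron miR-62-3p (0.43 ± 0.14) passed as higher, 2 arms of the miR-58 family as lower and 1 of the miR-51 family as lower. None of these lists passed camera in Adults. In bias-minimized Adults 0 arms of any list were called; adjusted over the list alone, 3 of 6 arms of the miR-72 family and 1 of the lin-4 family passed as lower, and 1 each of the miR-64, miR-238 and mirtron lists as higher.

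Whether the effect of an allele differed between L4 and Adult was tested as an interaction. For cdb330, 35 of 215 arms differed (22 higher in Adults than at L4, 13 lower; 16 and 6 at least 2-fold). The miR-35 family led, with 14 of 16 arms higher and 0 lower (median 1.60; 13 higher on the spike-in scale), for example miR-36-3p (2.02 ± 0.20, adjusted p of 2.02e-07 by edgeR's quasi-likelihood test) and miR-35-3p (1.59 ± 0.25), and camera gave it an adjusted p of 2.2e-17 (adjusted p = 0.0207 with an estimated correlation). miR-355-5p was less reduced in Adults (1.66 ± 0.17), and miR-790-5p (-1.71 ± 0.30), miR-253-3p (-1.61 ± 0.29), lsy-6-3p (-1.43 ± 0.48) and miR-241-5p (-0.82 ± 0.21) went the other way. In the let-7 family 0 arms were higher and 2 of 12 lower, with the same counts adjusted over the list alone. The split was 16 higher and 20 lower with total counts, 9 and 38 with mirtron scaling and 14 and 56 on the spike-in scale (median shift -0.58).

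For cdb328 only 7 arms had an effect that differed between stages (2 higher in Adults, 5 lower), while 52 had an unadjusted p under 0.05 and DESeq2 called 19 (7 higher, 12 lower). miR-355-5p was less reduced in Adults (1.27 ± 0.17, adjusted p of 3.64e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), as was miR-82-5p* (1.08 ± 0.30). More reduced were miR-71-5p (-0.69 ± 0.18), miR-72-5p (-0.55 ± 0.13), miR-73-3p (-0.59 ± 0.15) and miR-240-5p* (-0.80 ± 0.22). The change of miR-42-3p was also lower in Adults than at L4 (-0.89 ± 0.23), but at L4 it was not called lower. The split was 1 higher and 0 lower with DESeq2's size factors, 9 and 0 with total counts, 1 and 44 with mirtron scaling and 2 and 0 on the spike-in scale. In the miR-35 family 1 of 16 arms was lower (7 adjusted over the list alone; camera adjusted p of 4.58e-04, but adjusted p = 0.387 with an estimated correlation), and in the miR-72 family 2 of 6, whose median of -0.25 became 0.02 with total counts. Leaving out single libraries gave 1 call (cdb328 L4 replicate 1 or cdb328 Adult replicate 1), 2 (wild type L4 replicate 2 or cdb328 Adult replicate 3), 3 (wild type Adult replicate 3 or cdb328 Adult replicate 2) or 4 (wild type L4 replicate 1, wild type Adult replicate 1 or cdb328 L4 replicate 3).

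Compared directly, cdb328 lay below cdb330 for miR-71-5p (-4.03 ± 0.15 at L4, -5.07 ± 0.15 in NEBNext Adults and -4.79 ± 0.20 in bias-minimized Adults), miR-241-5p (-4.29 ± 0.17, -3.90 ± 0.17 and -4.36 ± 0.48) and miR-54-3p (-3.98 ± 0.13 and -3.94 ± 0.13 with NEBNext). miR-355-5p was the opposite, with cdb328 higher by 1.13 ± 0.13 at L4 and 0.74 ± 0.12 in NEBNext Adults, where mirtron scaling turned it to -0.04 and -0.35; in bias-minimized Adults it had 0.34 ± 0.16 and was not called. At L4 the miR-35 family was higher in cdb328 (14 of 16 arms, 15 adjusted over the list alone, and 0 lower; miR-36-3p 2.35 ± 0.15), with a camera adjusted p of 9.03e-07 (adjusted p = 0.397 with an estimated correlation). Of the let-7 family 6 of 12 arms were lower and 1 higher (0.0124, and adjusted p = 0.399 with an estimated correlation). In Adults the miR-72 family was lower (4 of 6 arms, 0 higher; 0.00689, and adjusted p = 0.0417 with an estimated correlation). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 134 arms at L4 (76 higher, 58 lower), 88 in NEBNext Adults (37 higher, 51 lower) and 69 in bias-minimized Adults (33 higher, 36 lower). At L4 the split was 48 higher and 83 lower with total counts, 9 and 160 with mirtron scaling and 15 and 141 on the spike-in scale (median shift -0.93). In NEBNext Adults it was 1 and 173 with mirtron scaling and 18 and 61 on the spike-in scale (shift -0.21), and in bias-minimized Adults 20 and 39 with total counts, 5 and 102 with mirtron scaling and 2 and 104 on the spike-in scale (shift -0.78).

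Wild-type Adults against L4 larvae gave the developmental background of these comparisons (n = 3 per group, NEBNext). All 16 arms of the embryonic miR-35 family were higher in Adults (median 1.88; 12 higher and 0 lower on the spike-in scale), led by miR-38-3p (3.14 ± 0.18, 8.79-fold), miR-41-3p (2.21 ± 0.25) and miR-35-3p (2.02 ± 0.18). The larval timers fell: lin-4-5p by 0.78, let-7-5p by 0.65 and the rarer arm miR-237-3p* by 2.62 (log2). In the let-7 family 7 of 12 arms fell and 0 rose, and in the lin-4 family 3 of 3 fell. miR-71-5p rose by 0.92 ± 0.13, miR-253-3p by 2.10 ± 0.21 and miR-51-5p by 1.32 ± 0.15, and miR-81-5p* fell by 1.98 and miR-62-3p by 0.53.

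The test (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) called 144 of 215 arms between wild-type stages, 62 higher and 82 lower in Adults (28 and 26 at least 2-fold). The split was 27 and 130 with total counts, 90 and 16 with mirtron scaling and 21 and 147 on the spike-in scale (median shift -0.77). Camera gave adjusted p of 2.14e-15 for the miR-35 family (adjusted p = 0.0309 with an estimated correlation), 0.0261 for the lin-4 family (adjusted p = 0.0715 with an estimated correlation) and 0.0350 for the miR-72 family (adjusted p = 0.0715 with an estimated correlation). In the miR-72 family 4 of 6 arms were higher and 0 lower, in the miR-64 family 6 of 10 and 0 and in the miR-238 family 4 of 5 and 0, but on the spike-in scale their medians of 0.52, 0.44 and 0.59 became -0.23, -0.32 and -0.17. The miR-58 family had 4 of 9 arms higher and 4 lower, the miR-44 family 2 of 7 higher and 4 lower, the miR-51 family 3 of 11 higher and 2 lower, and the neuronal list 0 of 4 higher and 1 lower. Adjusted over the list alone the miR-51 family had 2 higher and 1 lower, the neuronal list 0, and the other counts were the same.

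The tagged Adults with the term drsh-1(null) in their genotype differed from those without it in 9 arms on the TMM scale, and on the spike-in scale in 67, all lower and 24 of them at least 2-fold (n = 2 per group). miR-355-5p was higher (0.68 ± 0.16) but had -0.05 on the spike-in scale, miR-41-3p (0.95 ± 0.28) and miR-786-3p (0.85 ± 0.24) were higher on the TMM scale, and miR-253-5p* was lower (-1.09 ± 0.25); miR-71-5p (0.22 ± 0.16) and miR-80-3p (0.30 ± 0.14) were not called. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 9 of 215 arms (8 higher, 1 lower), with adjusted p of 0.0233 for miR-355-5p, 41 arms had an unadjusted p under 0.05, and DESeq2 called 11 (7 higher, 4 lower). With other scalings the split was 0 and 1 (DESeq2's size factors), 2 and 3 (total counts), 0 and 0 (mirtrons) and 0 and 67 (spike-ins, median shift -0.69). The miR-35, miR-58 and miR-238 families had 1 higher arm each and the other lists 0 (2 in the miR-238 family adjusted over the list alone). On the TMM scale every library decided the count: it was 0 without tagged replicate 1 or replicate 2, 5 without tagged/null replicate 1 and 4 without replicate 2. No library was left out on the spike-in scale. miRNA reads over the spike-in size factor were 0.625-fold in the second group (0.697-fold over summed spike-in reads, with an exact permutation p of 0.333 for both, the smallest that 2 against 2 libraries allow). On the log2 scale this ratio was 3.09 and 2.88 in tagged replicates 1 and 2, and 1.95 and 2.66 in tagged/null replicates 1 and 2. The lower arms on the spike-in scale thus rest on a common shift that came largely from tagged/null replicate 1.

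The mir-80 series asked whether changes in mir-80 alter how much its product depends on drsh-1. With drsh-1 intact, miR-80-3p fell in every allele: by a log2 of 5.28 in cdb493, 3.19 in cdb496, 1.92 in cdb530, 1.74 in cdb495 and 1.45 in cdb494. With only the groups compared in the fit, cdb494 (-1.36, adjusted p of 0.123 by edgeR) and cdb495 (-1.77, 0.0534) were not called, nor was cdb494 with mirtron scaling (-0.96, 0.291). The drsh-1 mutation itself left miR-80-3p from wild-type mir-80 at -0.10 ± 0.16. On cdb496 it lowered miR-80-3p by a further -2.41 ± 0.17, on cdb493 by -1.73 ± 0.19 and on cdb530 (with drsh-1(cdb328) in place of cdb263 cdb328) by -1.64 ± 0.19. On cdb494 and cdb495 miR-80-3p had 0.20 ± 0.18 and 0.07 ± 0.18 and was not called. As CPM, miR-80-3p went from 9068.7 ± 1035.4 (SD, n = 3) to 1664.0 ± 430.2 (n = 3) in cdb496, and from 22772.7 ± 472.2 (n = 2) to 20191.1 ± 1253.7 (n = 3) in cdb495.

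The difference between the drsh-1 effect on an allele and that on wild-type mir-80 was tested directly. It was -2.31 ± 0.23 for cdb496 (adjusted p of 3.25e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), -1.63 ± 0.25 for cdb493 (3.06e-04) and -1.54 ± 0.25 for cdb530 (5.04e-04), and 0.29 ± 0.25 for cdb494 (0.929) and 0.16 ± 0.25 for cdb495 (0.998). The reference for cdb530 is the effect of cdb263 cdb328, not of cdb328 alone. The passenger arm miR-80-5p* behaved alike on cdb496 (-2.80 ± 0.30) and cdb530 (-1.86 ± 0.31), and on cdb493 it had -1.06 ± 0.33 and did not pass. Each comparison of 3 against 3 or 3 against 2 libraries had an exact permutation p of 0.1, the smallest possible, except the drsh-1 effects on cdb494 (0.7) and on wild-type mir-80 (1). On cdb495 the libraries did not overlap in CPM, where the drsh-1 mutants lay 0.18 lower on the log2 scale (-0.18), while the TMM scale gave 0.07. With mirtron scaling the differences were -1.71 for cdb493 (adjusted p of 0.943) and -1.27 for cdb530 (0.462), and with only the groups compared in the fit the cdb493 difference was -1.71 (0.0556).

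**Figure D3:**
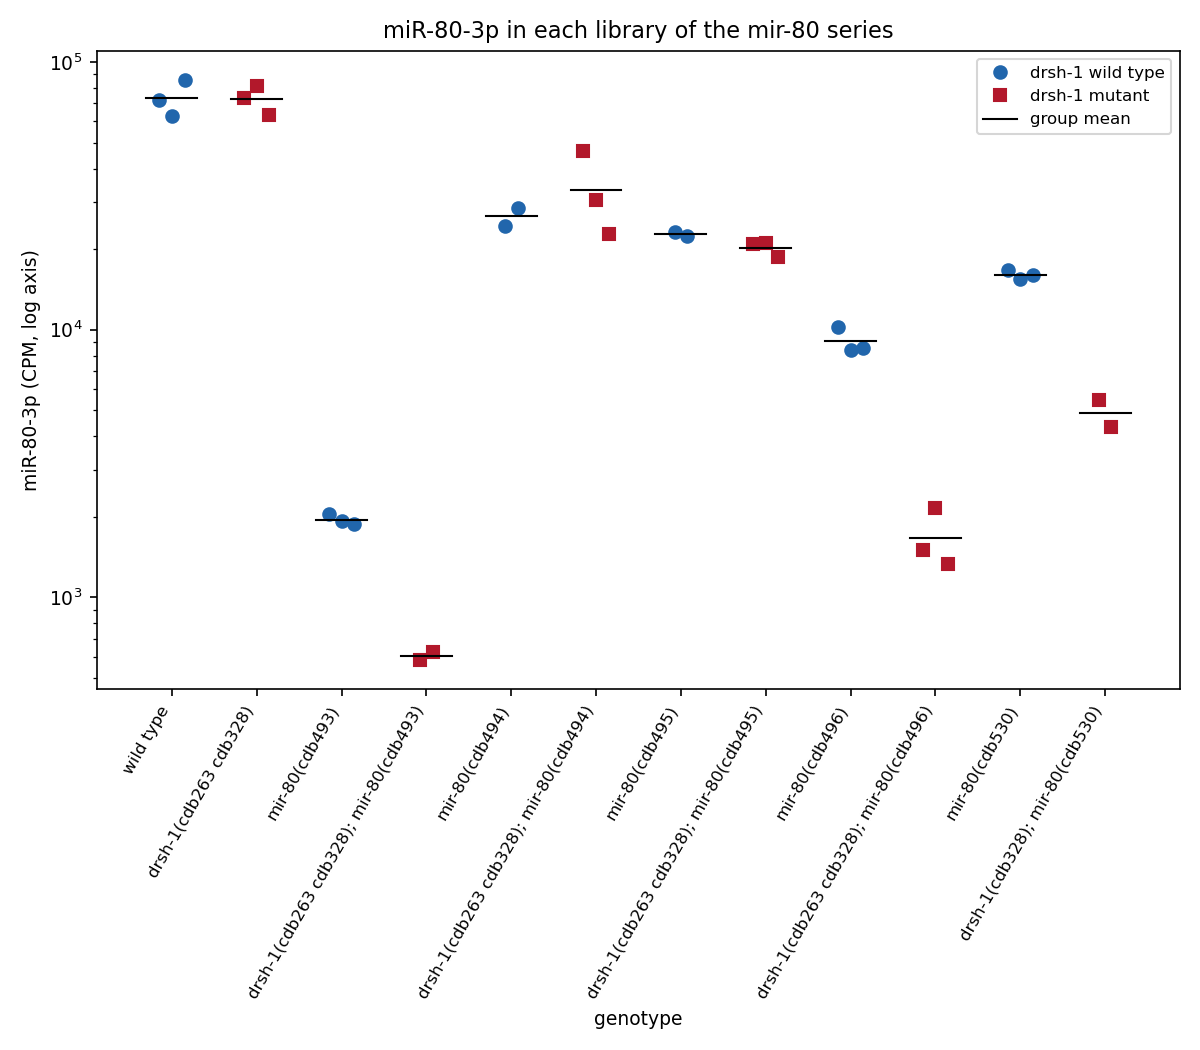
Level of miR-80-3p in CPM (y axis, log scale) in each library of the mir-80 series, by genotype (x axis), with drsh-1 intact (circles) or mutant (squares); black lines are group means. The drsh-1 mutant libraries lie below those of the same mir-80 allele for cdb493, cdb496 and cdb530, overlap them for wild-type mir-80 and cdb494, and lie just below them for cdb495.

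Against wild type with drsh-1 intact, cdb493, cdb494 and cdb496 had only the 2 arms of mir-80 called by edgeR's quasi-likelihood test, while 17, 32 and 27 arms had an unadjusted p under 0.05. On cdb495 12 arms were lower and 0 higher (40 at unadjusted p under 0.05), among them miR-42-3p by 1.08 and miR-35-3p by 1.48 (log2). In the fit without the lost miRNAs and those of wide range 7 of the 12 were still called. On the spike-in scale only the 2 arms of mir-80 were called. The difference of the drsh-1 effect on cdb495 was 2.00 ± 0.28 for miR-42-3p, which rests on the same cdb495 and wild-type libraries, and 0 arms of this difference were called on the spike-in scale. On cdb530 26 arms were called (9 higher, 17 lower; 68 at unadjusted p under 0.05), and on the spike-in scale 2 were higher and 25 lower. Falls besides mir-80 included miR-795-5p (-2.05 ± 0.29) and miR-360-5p (-3.38 ± 0.66, not called with only the groups compared), while the largest rises, miR-75-3p (7.28 ± 2.27) and miR-236-3p (6.85 ± 2.25), belong to the 20 miRNAs of wide range and are not read. The spike-in miR169a was almost lost from all 3 wild-type libraries of the series and from 0 of 3 of cdb530 and 0 of 2 of cdb494, so genotype and technical class coincide in these comparisons. With the class as a covariate, estimated from the other groups, 19 arms were called on cdb530 (5 higher, 14 lower), 17 of them among the 26, and miR-80-3p stayed called on cdb530 (-1.97) and cdb494 (-1.50). The labels do not say what each allele changes. If an allele alters the mature sequence its reads may be counted in part only, or together with those of relatives; a drsh-1 effect within an allele compares the same sequence, but how its reads were counted was not checked.

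The changes of the 5p and 3p arms of a hairpin were correlated in cdb328, although many pairs had opposite signs. Across 86 hairpins with both arms tested, Pearson r was 0.730 at L4 and 0.725 in Adults (permutation p of 1e-05 for both, Benjamini-Hochberg adjusted 1.75e-05 over 14 comparisons) and Spearman rho 0.318 and 0.453 (adjusted 0.00451 and 2.33e-05). Over 76 hairpins with the bias-minimized protocol r was 0.651 and rho 0.414 (adjusted 1.75e-05 and 3.68e-04). In the mir-80 series the correlation for cdb263 cdb328 was r = 0.327 and rho = 0.492 (adjusted 0.00434 and 2.33e-05). The sign was the same for 42 of 86 hairpins at L4, 51 of 86 in Adults, 44 of 76 with the bias-minimized protocol and 57 of 86 in the mir-80 series. Over the 21 hairpins with both arms at 100 CPM or more, Adult rho was 0.362 (permutation p of 0.11, adjusted 0.171) and r 0.887 (adjusted 0.00215), so r rests in part on a few large falls; at L4 rho was 0.682 (adjusted 0.00397). The sets are hairpins, which are not independent replicates.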

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

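The tests of the miRNAs lost from some bias-minimized libraries, of arms and pairs left out or counted for the cdb328 falls, of the miR-35 family in cdb330 Adults and of the cdb328 falls with the bias-minimized protocol were chosen after the results were seen.

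Effects that differed between groups by a test of the difference itself were these. The effect of cdb330 differed between L4 and Adults for 35 miRNA arms and that of cdb328 for 7. The drsh-1 effect on miR-80-3p differed from that on wild-type mir-80 by -1.63 (log2) on cdb493, -2.31 on cdb496 and -1.54 on cdb530.

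Genotype labels were shuffled within each stage for the interactions. Of 100 splits, the real one included, 3 gave at least the 35 calls of cdb330, a share under the stated bound of 0.05. Shuffling also breaks up the genotype effect within each stage, so this test cannot exclude chance for the interaction. The highest of the others gave 41 without being an exchange at one stage. It kept 0 of 6 own labels at L4 and 2 of 6 in Adults, and is thus close to the real split with the genotype names swapped. For cdb328 12 of 100 gave at least 7, with a highest of 78, so chance is not excluded. All 11 others for cdb328 exchanged most genotype labels at one stage only, which carries the genotype effect itself into the term; the highest split that did not do so gave 0. The other comparisons allow only 10 splits, too few for a share under 0.05. The highest other split gave 0 calls for cdb328 L4 (123 calls), cdb330 L4 (66), cdb328 against cdb330 at L4 (134) and in NEBNext Adults (88), wild-type Adult against L4 (144) and bias-minimized cdb330 (1). It gave 1 for cdb328 Adult (106), 2 for cdb330 Adult (16) and cdb328 against cdb330 in bias-minimized Adults (69), 5 for bias-minimized cdb328 (94) and 6 for cdb263 cdb328 in the mir-80 series (43). Where the numbers pair the samples, 4 splits part every pair, and the highest other of these gave 0 calls in all 3 bias-minimized Adult comparisons. The real splits gave 94, 1 and 69, and all of these splits were fitted without the replicate block. The other splits put both libraries of some number on the same side.

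For the set of falls in cdb328, the first pattern, cloning bias of the NEBNext kit is argued against: of the 2-fold falls in NEBNext Adults that the bias-minimized protocol also tested, 88.6% (31 of 35) fell past the threshold there and 100% were negative. All of the 48 falls (100%) were also past the threshold and lower on the spike-in scale. In this comparison that scale moved fold changes further down, so the test cannot argue against a common scale. A variant linked to drsh-1 stays open: 9.52% of the fallen hairpins (4 of 42) lie on chromosome I, but only 11 of 127 tested hairpins lie there, so the stated bound of 50 percent was wrong, and a variant acting in trans could lower any hairpin. A step before Dicer stays open too, since the rho between arms was 0.453 over all hairpins but 0.362 at 100 CPM or more (permutation, adjusted 0.171), 51 of 86 had the same sign, and of 26 hairpins with a 2-fold fall the other arm was lower in 13, higher in 5 and not called in 8. Shared primary transcripts stay open as well: hairpins within 10 kb on the same strand differed less than random pairs (percentile 2.36), but 21 of the 52 pairs lie in the mir-35 to mir-41 cluster and the other 31 reached percentile 22.6 (median difference 0.732 against 0.877).

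The second pattern is the lower miR-35 family in cdb330 L4 worms, which may reflect the stage of the animals and not processing. Normalization is argued against by a median of -1.04 for the called members on the spike-in scale. Processing by the mutant protein at any stage is argued against by a median of -0.11 for the same members in cdb330 Adults. Younger or less fertile L4 animals would shift other miRNAs against the L4-to-Adult change, and over 199 miRNAs outside the family rho was -0.31 with that change in the cdb328 libraries (permutation p of 1e-04, the smallest that 10000 resamples give), which fits, but the animals' stage was not recorded in the labels beyond L4 and a stage-dependent need for drsh-1 remains untested.

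The third pattern is a set of miRNAs almost lost from some bias-minimized libraries. miR-44-3p had a median of 156.6 CPM in 15 libraries against 4777.7 in the other 26, and miR-45-3p 155.8 against 4808.4. Genotype is argued against, since 7 of the 12 genotype groups of the mir-80 series held libraries with and without the loss, and low depth is argued against by a median of 4510.3 expected reads in the affected libraries. The plant spike-in miR169a, which no worm makes, was low in the same libraries as miR-44-3p (at most 0.238% of spike-in reads against at least 3.53%; 100% agreement over 41 libraries), consistent with loss in library making or read processing. Not all lost miRNAs followed these libraries. miR-58a-3p was under 1% of miRNA reads in 9 libraries. miR-236-3p had 48.6 CPM in bias-minimized cdb330 Adult replicate 3, where miR169a was not low (4.94% of spike-in reads). No Adult library was low in miR169a (0), against 3 of wild type and 2 of cdb263 cdb328 in the mir-80 series. But 10 of 20 miRNAs of wide range within groups, miR-75-3p among them, varied so in Adult groups too, and their cause was not tested.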

How the results depend on the processing

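Spike-in scaling, the robust fit, the technical class and the fits without sets of miRNAs were chosen after seeing the data. Of 530 values of the 33 main results under alternatives, 479 kept their side of the threshold or stayed within 1.5 times the count. Counts were compared as totals of called arms, so a changed split between higher and lower arms was not scored. For cdb328 against cdb330 at L4, 76 higher and 58 lower arms became 15 and 141 on the spike-in scale and were scored as kept. The 479 values therefore do not show that the directions held. A change of sign was counted only where either fit passed the threshold, so values that stayed the same by this rule may differ in sign. Of 2731 values of named miRNAs, lists and correlations 2434 were the same, 256 lost their call (119 of them with 1 library left out, 30 each with mirtron and spike-in scaling) and 28 changed sign. The replicate block moved no count by that much and ended 3 calls of named miRNAs (94, 1 and 69 calls in the bias-minimized Adults; 125 for cdb328 L4 and 10 for the cdb328 interaction): lsy-6-3p in the cdb330 interaction (-1.43, adjusted p of 0.0521 by edgeR), and miR-236-3p (5.08, 0.125) and miR-79-3p (4.49, 0.178) for cdb263 cdb328 in the mir-80 series. Elsewhere the numbers do not pair the samples: same-numbered deviations correlated at a mean of 0.0112 in the NEBNext libraries, where 6 of 18 correlated best with their own number, and 0.0144 in the mir-80 series, where 11 of 32 did. The robust fit, the technical class and the fits without the lost miRNAs, the miRNAs of wide range or the miR-35 family moved no main result past these bounds, although without the miRNAs of wide range the mir-80 series had 23 higher and 25 lower arms. The robust fit ended 1 named call (miR-79-3p) and the technical class 4, all of miR-75-3p, miR-79-3p or miR-236-3p. The cause was not tested for any change named here, except that mirtron scaling sets miR-62-3p, which rose in cdb328, to nearly no change by construction. At the depth and spread of the bias-minimized Adults 25% of simulated 2-fold changes were recovered, and the share of each was not separated.

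With mirtron scaling the counts were 43 (cdb330 L4), 188 (cdb328 Adult), 45 (cdb330 Adult), 174 (cdb328 against cdb330 Adult), 45 (cdb328 interaction), 0 (tagged/null; 41 at unadjusted p under 0.05 in the main test, 11 by DESeq2), 32 (bias-minimized cdb330) and 107 (bias-minimized cdb328 against cdb330). Spike-in scaling gave 80 (cdb328 L4), 143 (cdb330 L4), 2 (cdb328 interaction), 70 (cdb330 interaction), 67 (tagged/null), 2 (bias-minimized cdb330), 106 (bias-minimized cdb328 against cdb330) and 24 (mir-80 series). The cdb328 interaction gave 1 with DESeq2's size factors, 2 without filter, 19 with DESeq2 and 11 with only the groups compared. The tagged/null comparison gave 1 with DESeq2's size factors, 5 with total counts, 1 without filter and 0 with only the groups compared. Bias-minimized cdb330 gave 7 with DESeq2's size factors, 10 with total counts and 23 with DESeq2. Leaving out 1 library at a time gave 1 to 9 calls (cdb328 interaction), 0 to 5 (tagged/null), 10 to 18 (cdb330 Adult), 1 to 4 (bias-minimized cdb330) and 28 to 36 (mir-80 series). miR-80-3p lost its call with mirtron scaling for the difference on cdb493 (-1.71, adjusted p of 0.943), cdb494 against wild type (-0.96, 0.291) and the difference on cdb530 (-1.27, 0.462), and with only the groups compared for the difference on cdb493 (-1.71, 0.0556), cdb494 (-1.36, 0.123) and cdb495 (-1.77, 0.0534) against wild type. Of 15 list calls 6 held with an estimated correlation.

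Single miRNAs changed sign, with a call in either fit, as follows. Mirtron scaling gave, in cdb328 L4, let-7-5p -0.78, lin-4-5p -0.89, miR-1-3p -0.57, miR-238-3p -0.27, miR-44-3p -0.61, miR-45-3p -0.61, miR-48-5p -0.70, miR-64-5p -0.19 and miR-80-3p -0.58. In cdb328 Adults it gave lin-4-5p -1.51, lsy-6-3p -0.33, miR-1-3p -1.32, miR-238-3p -0.50, miR-44-3p -1.01, miR-45-3p -1.03, miR-1829a-3p* -0.77, miR-48-5p -1.57, miR-64-5p -0.81 and miR-80-3p -0.94. It gave in cdb330 Adults miR-80-3p -0.0748, in cdb328 against cdb330 miR-355-5p -0.0351 at L4 and -0.35 in Adults, and miR-64-5p -0.15 and lin-4-5p -0.87 in bias-minimized cdb328 and miR-64-5p -0.33 in the mir-80 series. Spike-in scaling gave miR-71-5p 0.0920 and miR-80-3p 0.33 in cdb330 L4 and miR-355-5p -0.0535 in tagged/null.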

Other observations

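Neighbouring hairpins differed strongly at some places in cdb328 Adults. mir-71 and mir-2 lie in introns of ppfr-1 on the same strand (mir-2 at I:9372768-9372865). Their mean log2 fold changes were -5.35 and -0.66. mir-54 fell 3.65 further than mir-55 and 3.78 further than mir-56, its neighbours within 10 kb on X, mir-241 3.57 further than mir-48 on V, mir-790 5.13 further than mir-228 on IV and mir-73 2.08 further than mir-74 on X (log2). Over all 52 such pairs the median difference was 0.552 (random pairs 0.881), but 21 of them lie within the mir-35 to mir-41 cluster, and over the other 31 it was 0.732 (random pairs 0.877). These pairs were chosen after their values were seen.

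Beside the rarer strands of mir-44 and mir-80, miR-45-5p* fell by 1.01 at L4 and 1.25 in Adults, miR-81-5p* by 1.49 and 1.17 and miR-82-5p* by 2.05 and 0.97 (log2), while miR-45-3p rose by 0.47 and 0.53 on the TMM scale (negative with mirtron scaling). Other falls were miR-788-3p (-1.62 ± 0.17 and -1.76 ± 0.19), miR-1817-5p (-1.75 ± 0.14 and -1.83 ± 0.16) and miR-2210-3p (-1.88 ± 0.25 and -2.51 ± 0.29). miR-1829a-3p* rose (1.27 ± 0.12 and 0.77 ± 0.13) and was higher in 8 of the 9 drsh-1 comparisons, although with mirtron scaling it had -0.77 in Adults. These miRNAs were named after their values were seen.

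The miR-35 family moved with a mir-80 allele. In cdb495 with drsh-1 intact 8 of its 16 arms were lower than in wild type and 0 higher (median -1.13; 13 lower adjusted over the list alone). Camera gave an adjusted p of 1.66e-10 (adjusted p = 0.0306 with an estimated correlation). On the spike-in scale the median was -0.94 and 0 arms were called. In this family miR-35-5p*, miR-36-5p* and miR-41-5p* are among the 20 miRNAs of wide range within groups. In cdb494 and cdb496 0 arms were called, and in cdb530 4 were higher (median 0.41, -0.19 on the spike-in scale). The stage of these worms is not in the labels, and cdb495 with drsh-1 intact has 2 libraries.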
